A study of Mus musculus with 3 samples.

How the data were processed

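Gene expression was measured in single cells of left perilesional brain tissue from male C57BL/6 mice aged 6 to 8 weeks, in 3 libraries. The groups were sham, traumatic brain injury (TBI) with phosphate-buffered saline (TBI+PBS) and TBI with interleukin-25 (TBI+IL-25), with 1 library per group. Per the labels, each mouse of that group got 1 µg of IL-25 no later than 30 minutes from injury, and further daily doses over 3 days. Per the labels' protocols, tissue was digested with collagenases and neutral protease, red cells were lysed and dead cells were removed. The suspension was then loaded on a 10x Chromium 3' kit for 8000 expected cells and read as 150 bp pairs. The labels do not say how many animals went into a library.

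The deposited matrices hold raw UMI (unique molecular identifier) counts per gene and barcode, with no normalization. Per the file headers, the authors' software was Cell Ranger 7.1.0 for sham and TBI+PBS and Cell Ranger 7.2.0 for TBI+IL-25. The submitters' processing notes name Cell Ranger 7.2.0, bcl2fastq 5.0.1, Seurat 4.4.0 and the build GRCm39. No source says how barcodes were selected. The lowest total per barcode was 500 or 501 UMIs in every library. Each matrix lists 55357 genes, and identifiers and symbols were taken as deposited. No coordinates are given, because the reference used by the submitters and the annotation at hand are of different builds.

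Everything below was computed here from those counts. Cells with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were kept. Doublets were scored per library with Scrublet in scanpy 1.11.5. The automatic threshold marked only 3 sham cells (0.0336%), so 1 score threshold of 0.2 was set for all libraries after the scores were seen. It removed 222 sham, 299 TBI+PBS and 636 TBI+IL-25 cells (2.49%, 2.82% and 4.49%). The filter removed a further 18, 43 and 55. The labels' 8000 expected cells stand beside 8939, 10643 and 14222 deposited barcodes and 8699, 10301 and 13531 kept cells.

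Cells were clustered jointly on log-normalized counts of 2000 variable genes, with 30 principal components, 15 neighbours, shared-neighbour weights and Leiden clustering at resolution 1 (leidenalg 0.10.2, python-igraph 0.11.9), without batch integration. Mitochondrial, ribosomal-protein, haemoglobin, Xist, Malat1 and Rn18s genes were left out of the variable genes. The other tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and Matplotlib 3.10.9. The 31 clusters were named from 21 cell type marker lists, fixed in advance. A marker counted as present when at least 20% of a cluster's cells held it at 2 or more times the median level over clusters. The class with the largest share of its markers present gave the name. A cluster stayed unnamed with fewer than 3 markers, or with more markers of another class than of its own among its top 10 genes by fold. It also stayed unnamed when its median UMI count was below its library's median divided by 3 and none of its own markers was among those 10 genes. These thresholds were set after the data were seen. They gave 13 named classes, all called "like" below, and left out cluster 6. This shallow cluster held 9 of 10 astrocyte markers and made up 0.0115% of sham, 3.85% of TBI+PBS and 10.4% of TBI+IL-25 cells. Border-associated macrophages, dendritic cells, natural killer cells, type 2 innate lymphoid cells (ILC2), mast cells, neurons, oligodendrocyte precursors and erythroid cells formed no class of their own at this resolution.

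UMIs were summed per library and class and given as CPM, the UMIs of a gene scaled to a common class total. Sums carry exact Poisson intervals, ratios of CPM exact conditional binomial intervals and shares of cells Clopper-Pearson intervals. All are 95% intervals and cover counting error only. A count of 0 is given with the limit of 3 counts. A fold against 0, written as "at least", was computed with 3 counts per library and class in place of the 0. It takes the other count as exact and is no 95% bound. The bound of the 95% interval is less extreme, for Lcn2 in astrocyte-like cells 774-fold against 952-fold. Cells are not replicates, so no p-value, standard error or count of changed genes is given. With 1 library per group there is no replicate check, and leaving out a replicate was not possible.

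The 19 response lists were fixed before the data were examined, together with the comparisons, the marker lists and the rule for named genes. The lists covered tight and adherens junctions, blood-brain barrier transport, endothelial activation, angiogenesis, matrix proteases and inhibitors, the CXCR3 axis, interferon-stimulated genes and type 2 cytokines. They also covered IL-25 and type 2 receptors, alternative activation, proinflammatory cytokines and chemokines, homeostatic and disease-associated microglia, MHC class II presentation, complement, reactive astrocytes, hypoxia and glycolysis, dissociation and immediate early genes, and proliferation. A list's value is the median log2 CPM ratio of its members with at least 50 UMIs in the 2 libraries together, with an interval from 1000 Poisson draws. Members are counted as higher or lower by their ratio alone, whether or not its interval reaches 1. Its percentile among 10000 random lists of the same size, matched on mean expression, describes these libraries only. Of the 13 homeostatic microglia genes, 9 are also markers that defined the microglia-like class. Cldn5, Pecam1, Flt1, Kdr, Cdh5, Slco1a4 and Abcb1a are likewise markers of the endothelial-like class. The median log2 ratio of all genes was -0.15 in microglia-like cells for TBI+PBS against sham and -0.19 in astrocyte-like cells for TBI+IL-25 against TBI+PBS, and list values there should be read relative to it.

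Named genes were, in the endothelial-like, microglia-like and the 2 other comparable classes with most cells (at least 100 per library), the 3 genes with the highest and the 3 with the lowest CPM ratio. They were ranked by the interval bound nearest to 1 among genes with at least 50 UMIs. Mitochondrial, ribosomal-protein, haemoglobin, Gm-numbered, Rik, Xist and Y-linked genes and markers of other classes were left out. Members of the response lists were named as well, with Cxcl10, Cldn5, Ocln, Tjp1, Il13, Il5, Il17rb and Il1rl1 always.

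On simulated counts with 200 changed genes, intervals covered the true ratio of unchanged genes in 95.7% and 95.6% of cases in microglia-like cells, for TBI+PBS against sham and for TBI+IL-25 against TBI+PBS. In endothelial-like cells the coverage was 96.5% and 96.3%. A 2-fold higher gene was separated from 1 in 96.0% and 100% of microglia-like cases, and in 56.0% and 85.7% of endothelial-like cases. Random lists had mean percentiles of 49.1 to 51.2. The simulations held counting error alone and no spread between animals.

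Alternatives tried were a stricter and no cell filter, doublets kept, resolutions 0.5 and 2, classes from each cell's own marker score, median-of-ratios size factors, the mean over cells, subtraction of free RNA, other count minimums and thinning of cells to 1000 UMIs. Others were added after the data were seen and are named with their values in the closing section.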

Results

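RNA of single cells from the left perilesional brain was counted in 3 libraries, 1 each from sham mice, mice with TBI given PBS and mice with TBI given IL-25. The sham library held 39536447 UMIs over 8939 barcodes, TBI+PBS 58148289 over 10643 and TBI+IL-25 61372408 over 14222. Kept cells had a median of 4109, 4666 and 3840 UMIs and 1999, 2177 and 1825 genes. Each group had 1 library, so each difference below compares libraries and not conditions. The TBI+IL-25 library also differed in kind. Ribosomal RNA took 0.176% of UMIs in sham, 0.203% in TBI+PBS and 2.01% in TBI+IL-25, and haemoglobin genes stood at 98.9, 111 and 0.13 CPM. Cells under 1000 UMIs made up 6.41%, 7.49% and 10.8%. The Cell Ranger version in the file header also separated TBI+IL-25 from the other libraries, so none of these differences can be told apart from the treatment.

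Microglia-like and astrocyte-like cells made up most of every library. Microglia-like cells were 57.4% of sham (95% interval 56.4% to 58.5%), 44.6% of TBI+PBS (43.7% to 45.6%) and 41.0% of TBI+IL-25 cells (40.1% to 41.8%). Astrocyte-like cells were 37.7% (36.7% to 38.7%), 40.2% (39.2% to 41.1%) and 39.0% (38.2% to 39.8%). The same class name covered different clusters in each library. Of the microglia-like cells, cluster 0 held 70.6% in sham and cluster 1 held 42.7% in TBI+PBS, while clusters 7, 1 and 5 held 28.5%, 24.8% and 21.3% in TBI+IL-25. Of the astrocyte-like cells, cluster 8 held 43.2% in sham, cluster 10 held 36.4% in TBI+PBS and cluster 2 held 56.7% in TBI+IL-25. Clusters 10 and 2 came to 98.2% and 98.9% from their own library, so they are not compared as cell types. Endothelial-like cells were few, at 36, 213 and 46 cells in 1 cluster, which sets the precision of every vascular value below.

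**Figure D1:**
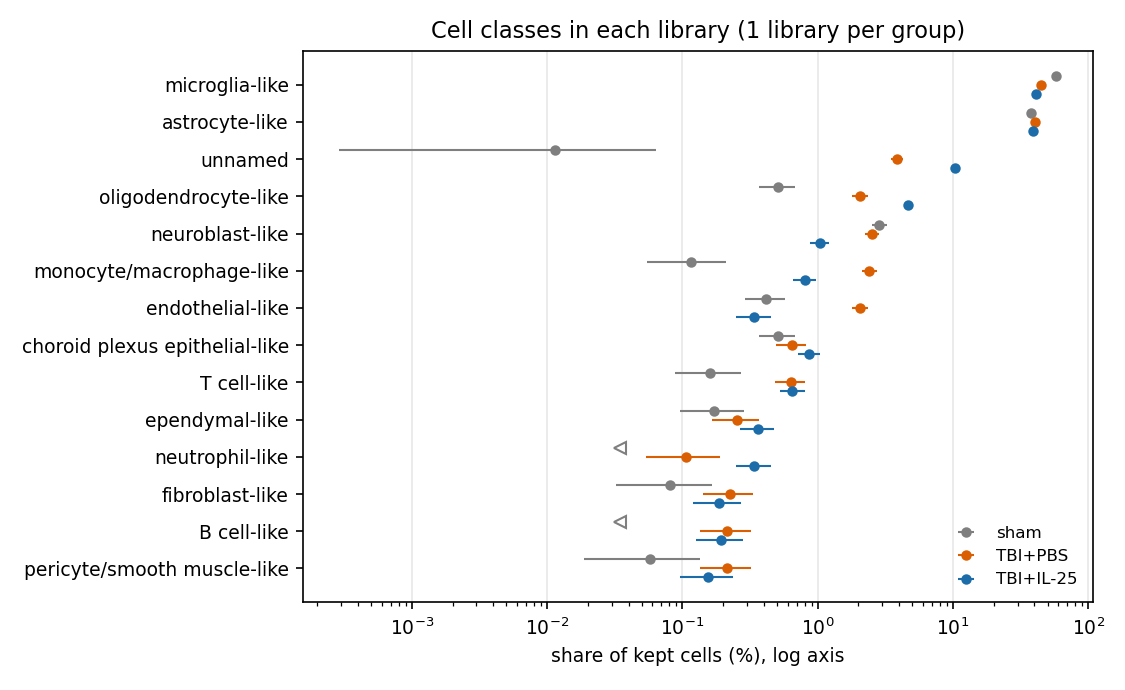
Share of kept cells (percent, log axis) in each named class and the unnamed cluster for the sham, TBI+PBS and TBI+IL-25 libraries, with exact 95% binomial intervals for counting error and open triangles for the limit of a count of 0. Endothelial-like cells were 0.414%, 2.07% and 0.340% of the 3 libraries, and monocyte/macrophage-like cells 0.115%, 2.41% and 0.806%.

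The first comparison, TBI+PBS against sham, addresses what injury did to the perilesional cells over 3 days. The TBI+PBS library held more blood-derived and vascular cells and a smaller share of microglia-like cells. Its microglia-like cells had less of the homeostatic genes, such as P2ry12, and far more of Spp1, Ccl7 and inflammatory chemokines. Its astrocyte-like cells had 20.2-fold more Gfap and, from 0 counts in sham, at least 952-fold more Lcn2. Endothelial-like cells had more activation and hypoxia genes and less of several barrier transporters. Cxcl10, a chemokine that draws T cells through the receptor CXCR3, stood at 12.5 CPM over all sham cells and 98.7 CPM over all TBI+PBS cells, 7.87-fold higher (7.17 to 8.67).

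Monocyte/macrophage-like cells were 0.115% of sham and 2.41% of TBI+PBS cells, 20.9-fold higher (11.2 to 44.2). T cell-like cells were 3.92-fold higher in share (2.18 to 7.57), in a class that also held other cells, as its sub-clusters below show. Neutrophil-like cells were 0 of 8699 in sham, which allows up to 0.0345%, and 11 of 10301 in TBI+PBS, at least 3.10-fold higher. B cell-like cells, also 0 in sham, numbered 22, at least 6.19-fold higher. Endothelial-like cells were 5.00-fold higher in share (3.50 to 7.33) and oligodendrocyte-like cells 4.09-fold (2.94 to 5.79). Pericyte-like cells were 3.72-fold higher (1.37 to 12.6) and fibroblast-like cells 2.77-fold (1.15 to 7.66). The microglia-like share was 0.777-fold that of sham (0.747 to 0.809), the astrocyte-like share 1.07-fold (1.02 to 1.12) and the neuroblast-like share 0.878-fold (0.735 to 1.05). Ependymal-like and choroid plexus-like shares had ratios of 1.46 (0.747 to 2.97) and 1.27 (0.852 to 1.90).

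In microglia-like cells, whose largest clusters were cluster 0 in sham and cluster 1 in TBI+PBS, 12 of 13 homeostatic genes were lower, although 9 of the 13 also defined the class. Their median log2 ratio was -0.76 (-0.80 to -0.72), at percentile 0.01 of matched random lists. P2ry12, a purinergic receptor of resting microglia, was 0.368-fold the sham level (0.364 to 0.373), and Tgfbr1, a receptor for TGF-beta, 0.436-fold (0.427 to 0.446). Of 18 disease-associated microglia genes, 14 were higher, with a median of 0.86 (0.78 to 1.04; percentile 100). Spp1, which encodes osteopontin, went from 4.29 to 1721 CPM, 402-fold higher (324 to 503). Lgals3, encoding galectin-3, was 38.7-fold higher (30.0 to 50.9) and Lpl, encoding lipoprotein lipase, 16.4-fold (15.2 to 17.8). Proliferation genes were higher in 7 of 7 members, with a median of 2.21 (1.91 to 2.58; percentile 100). Mki67, a mark of cycling cells, was 10.6-fold higher (6.05 to 20.3).

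Inflammatory genes of the microglia-like class were higher too. Of 15 measured proinflammatory cytokines and chemokines, 13 were higher, with a median of 2.54 (2.40 to 2.71; percentile 100). Ccl7, which attracts monocytes, was 239-fold higher (130 to 498), Ptgs2, encoding cyclooxygenase-2, 44.2-fold (26.2 to 81.2), Ccl2 12.2-fold (11.3 to 13.2) and Il1b 9.97-fold (8.59 to 11.6). Il6 was 0.507-fold the sham level (0.415 to 0.619). Interferon-stimulated genes had a median of 0.37 (0.19 to 0.52; percentile 99.99), with 14 of 22 higher, and this direction was reversed to -0.41 with classes from each cell's own marker score and to -0.078 within cluster 4. Hypoxia and glycolysis genes were higher in 12 of 13 members (median 0.92, 0.88 to 1.05; percentile 100), among them Hmox1, encoding haem oxygenase-1, at 7.32-fold (6.81 to 7.88). Matrix proteases and inhibitors were higher in 5 of 7, 3 of them with intervals above 1 (median 0.41, 0.11 to 0.57; percentile 96.32), with the macrophage elastase Mmp12 at 54.3-fold (34.2 to 91.9). The gene Lilr4b, of the leukocyte immunoglobulin-like receptor family, was 120-fold higher (62.8 to 262). Much of this went with the clusters: within cluster 4, which both libraries fill, the medians were -0.18 for homeostatic, 0.19 for disease-associated, 0.26 for proinflammatory, 0.28 for hypoxia, 0.34 for proliferation and 0.079 for matrix genes. There Spp1 was 25.5-fold, Ccl7 9.48-fold, Lilr4b 2.21-fold and Cxcl10 1.41-fold the sham level. With classes from each cell's own marker score, Spp1 was 89.6-fold, Ccl7 88.7-fold and Lilr4b 21.4-fold higher, and the disease-associated median was 0.38. With cells weighed equally Spp1 was 241-fold higher, and after subtraction of free RNA the proliferation median was 3.90.

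Other lists were measured in the microglia-like class too, some of them made of genes of other cell types. Reactive astrocyte genes were higher in 7 of 7 measured members, with a median of 4.61 (3.98 to 4.86; percentile 100), or 1.34 within cluster 4, 3.59 with classes per cell and 3.83 after subtraction of free RNA. Blood-brain barrier transport genes were higher in 9 of 10, 6 of them with intervals above 1 (0.71, 0.49 to 0.80; percentile 99.97), or 0.28 within cluster 4. Complement genes were higher in 6 of 7 members (median 0.28, 0.27 to 0.29; percentile 78.96), with the C5a receptor C5ar1 at 5.79-fold (5.54 to 6.05). MHC class II genes were higher in 5 of 6 (0.23, 0.13 to 0.37; percentile 87.26), a direction reversed after subtraction of free RNA at -0.0665. IL-25 and type 2 receptors were higher in 4 of 7, with 2 intervals above 1 and 3 below (0.13, -0.15 to 0.42; percentile 85.51), and Il4ra, the shared receptor chain for IL-4 and IL-13, was 2.56-fold higher (2.41 to 2.73). Only 4 of 13 alternative activation genes were measured, with 3 lower (-0.21, -0.36 to -0.05; percentile 46.36). Dissociation and immediate early genes split evenly, 8 higher and 8 lower, with a median of -0.017 (-0.032 to -0.0017) that became 0.13 with median-of-ratios size factors and 0.023 without shallow clusters. At the low end stood Capn11, encoding a calpain protease, with 171 counts in sham and 0 in TBI+PBS, at least 73.2-fold lower. Klrd1, a lectin-like receptor of natural killer cells, was 0.0599-fold (0.0399 to 0.0870) and Ccdc162 0.0698-fold (0.0412 to 0.112), or 0.224-fold and 0.186-fold within cluster 4.

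The largest astrocyte-like clusters were cluster 8 in sham and cluster 10 in TBI+PBS, while clusters 3 and 9, filled by both libraries, held 26.4% and 19.5% of these cells in sham and 27.4% and 17.6% in TBI+PBS. All 12 measured reactive astrocyte genes were higher, with a median of 4.96 (4.77 to 5.46; percentile 100), and 2 of them had 0 counts in sham and entered at their bound. Lcn2, which encodes the iron-siderophore binding lipocalin-2, went from 0 to 3977 counts. Timp1, a metalloproteinase inhibitor, was 721-fold higher (247 to 3500) from 3 sham counts, and the small heat shock gene Hspb1 308-fold (184 to 564). The intermediate filament genes Gfap and Vim were 20.2-fold (18.9 to 21.5) and 8.52-fold higher (7.79 to 9.34). Tm4sf1, encoding a tetraspanin-like membrane protein, was 2233-fold higher (764 to 10830), also from 3 sham counts. Interferon-stimulated genes were higher in 17 of 18 members (1.63, 1.29 to 1.83; percentile 100), and Gbp2, an interferon-induced GTPase, was 19.1-fold higher (10.5 to 38.6). Proinflammatory genes were higher in 11 of 12 (2.42, 2.26 to 2.68; percentile 100) and hypoxia genes in 12 of 13 (0.45, 0.41 to 0.49; percentile 99.7). The proinflammatory median was 1.30 among members with at least 200 UMIs and 6.00 after subtraction of free RNA. Immediate early genes, which tissue digestion can raise, moved with them, higher in 15 of 16 (1.68, 1.54 to 1.85; percentile 100), with a median of 7.80 after subtraction of free RNA. Homeostatic microglia genes were lower in 10 of 13 members in these astrocyte-like cells (-0.48, -0.55 to -0.36), but their median was 1.23 after subtraction of free RNA. Other microglial lists went the opposite way: disease-associated genes were higher in 10 of 14 (0.51, 0.44 to 0.61; percentile 99.86), complement genes in 6 of 7 (0.21, 0.13 to 0.28; percentile 88.3) and MHC class II genes in 3 of 5 (2.42, 1.70 to 3.03; percentile 99.97). The disease-associated median was 0.17 among members with at least 200 UMIs and 0.87 after subtraction of free RNA, and the MHC class II median 1.61 without a count minimum. Lower genes included Rpe65, a retinoid isomerase, at 0.0499-fold (0.0349 to 0.0694), Apoa1, an apolipoprotein, at 0.0931-fold (0.0493 to 0.163), and the homeobox gene Rax at 0.110-fold (0.0562 to 0.198).

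In endothelial-like cells (36 against 213), 7 of 10 measured tight and adherens junction genes were higher, 4 of them with intervals above 1, with a median of 0.22 (0.03 to 0.46; percentile 87.92). Cldn5, the main claudin of brain endothelium and a marker that defined the class, went from 3057 to 4796 CPM, 1.57-fold (1.41 to 1.74). Ocln, encoding occludin, had a ratio of 1.15 (0.840 to 1.61) and Tjp1, encoding the scaffold ZO-1, of 1.02 (0.768 to 1.38), so no difference was detectable for them at this depth. Over all cells, Cldn5 was 8.24-fold higher (7.46 to 9.13), beside the 5.00-fold larger share of endothelial-like cells. Ocln was 1.89-fold (1.61 to 2.22) and Tjp1, also present outside endothelium, 0.855-fold (0.818 to 0.894). Blood-brain barrier transport genes were lower in 9 of 12 members, 6 of them with intervals below 1 (-0.35, -0.52 to -0.20; percentile 0.91), but their median was -0.15 at resolution 0.5 and -0.0905 when cells weighed equally. Mfsd2a, a lysophospholipid transporter that restrains transcytosis, was 0.433-fold (0.321 to 0.593), the transferrin receptor gene Tfrc 0.526-fold (0.402 to 0.699) and the organic anion transporter gene Slco1a4 0.646-fold (0.587 to 0.712). The glucose transporter gene Slc2a1 was 1.17-fold (1.06 to 1.29).

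Endothelial activation genes were higher in 6 of 8 members (1.79, 1.40 to 2.14; percentile 100), with 3 of them at 0 in sham and a median of 0.65 without a count minimum. Vwf, encoding von Willebrand factor, was 2.78-fold higher (1.66 to 5.02) and Lrg1, a vascular glycoprotein gene, went from 0 to 131 counts, at least 5.70-fold higher. The adhesion gene Icam1 had a ratio of 0.888 (0.455 to 1.94). Hypoxia genes were higher in 7 of 9, 5 of them with intervals above 1 (0.89, 0.26 to 1.27; percentile 100), with the vasodilator gene Adm at 11.1-fold (5.37 to 27.8). Angiogenesis genes were higher in 5 of 8, 4 of them with intervals above 1 (0.35, 0.03 to 0.91; percentile 74.97), a direction reversed to -0.17 among members with at least 200 UMIs. Interferon-stimulated genes were lower in 9 of 13 (-0.41, -0.63 to 0.10; percentile 1.2) and immediate early genes in 10 of 15 (-0.24, -0.41 to 0.02; percentile 1.44), both with intervals across 0 and with only 2 and 5 members whose own intervals lay below 1. Microglial genes were lower in the same cells, with all 11 measured homeostatic genes below sham, 10 of them with intervals below 1 (-1.35, -1.70 to -1.15; percentile 0.0) and medians of -0.70 for disease-associated and -0.61 for complement genes. The homeostatic median was -2.07 with classes per cell, -1.91 at resolution 0.5 and -0.75 with doublets kept, where the other 2 were -0.25 and -0.017. Without the cells holding 10 or more microglia marker counts it was -0.63 and the complement median 0.28. Reactive astrocyte genes were higher in 5 of 5 members, 3 of them with intervals above 1 (0.72, 0.48 to 1.80; percentile 99.51). Ranked by the interval bound nearest to 1, the 3 highest ratios were those of Ankrd37, a target of hypoxia-inducible factor, at 28.4 (7.82 to 235) from 2 sham counts, of Depp1, a FOXO target, at 15.0 (6.38 to 46.3), and of Ctla2a, a cysteine protease inhibitor, at 7.21 (5.96 to 8.82). The 3 lowest by the same rank were those of Basp1 at 0.232 (0.134 to 0.410), of the G-protein regulator gene Rgs10 at 0.249 (0.146 to 0.439) and of Selplg, the P-selectin ligand gene, at 0.280 (0.193 to 0.411). The Basp1 ratio was 0.573 with doublets kept, 0.811 with classes per cell and 0.0102 after subtraction of free RNA. The Selplg ratio was 0.436 with doublets kept and 0.179 with classes per cell, and the Rgs10 ratio 0.139 after subtraction. Selplg is also a homeostatic microglia gene, and 3 of 36 sham and 11 of 213 TBI+PBS endothelial-like cells held 10 or more microglia marker counts.

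In neuroblast-like cells (249 against 259), Tac2, the neurokinin B gene, went from 0 to 84 counts, at least 31.5-fold higher. Spp1 went from 0 to 61 counts, at least 22.8-fold higher, while it was also abundant in the microglia-like cells of the same library. Neurod1, a proneural transcription factor gene, was 69.6-fold higher (12.0 to 2794) from 1 sham count. Tac2, Spp1 and Neurod1 stood at 47.8, 34.7 and 35.3 CPM in TBI+PBS. Each had 0 counts in the 140 neuroblast-like cells of TBI+IL-25, with a limit of 3.71 CPM. The other injured library therefore did not share these higher values. Gsx1, a homeobox gene of ventral progenitors, was 0.174-fold (0.0831 to 0.331). The myeloid genes Mpeg1, encoding perforin-2, and Pycard, encoding the inflammasome adaptor ASC, were 0.295-fold (0.159 to 0.517) and 0.306-fold (0.171 to 0.522), or 0.622-fold and 0.718-fold with doublets kept. Homeostatic microglia genes were lower in 11 of 13 members in the same neuroblast-like cells (-0.68, -0.97 to -0.46), with a median of -0.24 at resolution 2, -1.0 with classes per cell and 2.49 after subtraction of free RNA. Oligodendrocyte-like cells (44 in sham) were too few for named genes, and 12 of their 15 measured immediate early genes were higher (1.02, 0.65 to 1.53; percentile 100). Genes of other cell types were higher in them too, with medians of 0.66 for homeostatic microglia (8 of 11 members), 0.70 for disease-associated (9 of 10), 1.83 for complement (5 of 5) and 4.91 for reactive astrocyte genes (3 of 3). With cells weighed equally the homeostatic median was -0.065. After subtraction of free RNA it was 1.34 and the complement median 4.04, and without a count minimum the reactive astrocyte median was 2.41.

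The second comparison, TBI+IL-25 against TBI+PBS, addresses what IL-25 given after injury did to perilesional tissue, with CXCL10 and the blood-brain barrier as the series' themes. The tissue pieces may have come from different brain regions, as the closing section weighs. Whether this affected the shares of cell classes was not tested. Cxcl10 was higher with IL-25, at 335 against 98.7 CPM over all cells, 3.40-fold (3.30 to 3.50). Ifnb1, the interferon beta gene, and interferon-stimulated genes were higher in microglia-like cells, while Spp1, Gpnmb and Igf1 of the disease-associated list were lower. Endothelial-like and monocyte/macrophage-like cells made up smaller shares, and all 12 barrier transport genes were lower in the few endothelial-like cells of TBI+IL-25. Cldn5 stood at 1.24-fold within endothelial-like cells (1.16 to 1.32), a direction that turned with the way cells were assigned to the class.

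Endothelial-like cells were 0.340% of TBI+IL-25 cells (0.249% to 0.453%) against 2.07% of TBI+PBS cells (1.80% to 2.36%), a ratio of 0.164 (0.117 to 0.227). Monocyte/macrophage-like cells were 0.806% against 2.41%, a ratio of 0.335 (0.265 to 0.421), and neuroblast-like cells 1.03% against 2.51%, a ratio of 0.412 (0.333 to 0.507). Oligodendrocyte-like cells were 4.66% against 2.07%, 2.26-fold higher (1.93 to 2.65), and neutrophil-like cells 3.18-fold higher (1.62 to 6.82). T cell-like and B cell-like shares had ratios of 1.03 (0.740 to 1.44) and 0.90 (0.490 to 1.67). Microglia-like and astrocyte-like shares had ratios of 0.918 (0.883 to 0.955) and 0.971 (0.932 to 1.01). The astrocyte-like ratio became 1.12 when the unnamed cluster 6 was counted as astrocyte. With classes from each cell's own marker score, the ratios were 0.314 for endothelial-like, 0.715 for monocyte/macrophage-like, 0.699 for neuroblast-like and 1.84 for T cell-like cells. Pericyte-like and fibroblast-like ratios were 0.727 (0.380 to 1.39) and 0.827 (0.451 to 1.53), and ependymal-like and choroid plexus-like ratios 1.43 (0.874 to 2.41) and 1.35 (0.990 to 1.85). Set against sham, the TBI+IL-25 endothelial-like share had a ratio of 0.821 (0.520 to 1.31), the monocyte/macrophage-like share 7.01 (3.67 to 15.0) and the microglia-like share 0.714 (0.687 to 0.742).

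Most Cxcl10 counts came from microglia-like cells, 56.7% of them in TBI+PBS and 75.2% in TBI+IL-25. In this class, with cluster 1 the largest in TBI+PBS and clusters 7, 1 and 5 in TBI+IL-25, Cxcl10 went from 123 to 505 CPM, 4.11-fold (3.95 to 4.27), after 23.7 CPM in sham. The share of microglia-like cells with a Cxcl10 UMI was 1.64%, 7.44% and 25.9% in sham, TBI+PBS and TBI+IL-25, at median depths of 3913, 4746 and 4731 UMIs. Oligodendrocyte-like cells were taken as a background, although they were not shown to lack the gene. Their share with a Cxcl10 UMI was 0 of 44 (up to 6.82%), 2.82% and 1.90%, at median depths of 10324, 8401 and 3917 UMIs. Astrocyte-like cells stood at 0.543, 72.6 and 202 CPM, 2.78-fold higher with IL-25 (2.62 to 2.95), or 4.50-fold with classes per cell. The ratio of TBI+PBS to sham there was 134, from 8 sham counts, or 43.4 with doublets kept. Their shares with a UMI were 0.244%, 2.51% and 5.87%, at median depths of 4513, 4627 and 3535 UMIs. The sham and TBI+PBS shares lie within the oligodendrocyte-like level or its limit, but oligodendrocyte-like cells were deeper there. By CPM, the astrocyte-like 72.6 in TBI+PBS lay above the 16.0 of oligodendrocyte-like cells, whose 34 counts lay in 6 cells. Monocyte/macrophage-like cells had 0 counts in sham, then 241 and 115 CPM, a ratio of 0.478 (0.369 to 0.611). In endothelial-like cells Cxcl10 had 0 counts in sham, 7 in TBI+PBS and 48 in TBI+IL-25, a ratio of 37.5 (16.8 to 98.1). The 48 counts lay in 2 of 46 cells, both with many microglia marker counts, and without the 6 endothelial-like cells holding 10 or more such counts no Cxcl10 count was left in 40 cells, against 7 in 202 TBI+PBS cells, too few to give a direction. Over all cells, TBI+IL-25 stood 26.7-fold above sham (24.4 to 29.4).

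**Figure D2:**
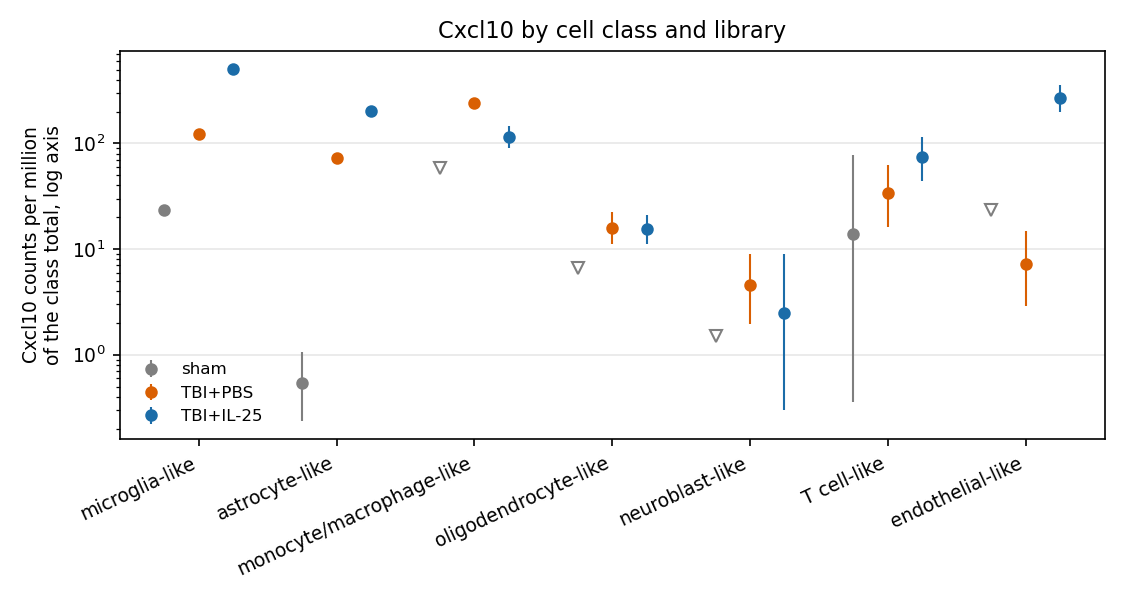
Cxcl10 in CPM of the class total (log axis) in the main classes of the sham, TBI+PBS and TBI+IL-25 libraries, with exact 95% Poisson intervals for counting error and open triangles for the limit of 3 counts where none was seen. Microglia-like cells stood at 23.7, 123 and 505 CPM, and the TBI+IL-25 endothelial-like value rests on 2 cells.

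The genes of the CXCR3 axis, with fewer than 3 members measured in most classes, are given gene by gene for microglia-like cells. Cxcl9, a sister chemokine, had 0, 8 and 9 counts in sham, TBI+PBS and TBI+IL-25, and Cxcl11 2, 8 and 91, which was 10.2-fold higher with IL-25 (4.97 to 24.4). Cxcr3, the receptor, had 41, 14 and 4 counts there. In T cell-like cells Cxcr3 had 11, 50 and 25 counts, a ratio of 0.571 with IL-25 (0.339 to 0.941). That class held different sub-clusters in each library, as given below. Over all cells, Cxcr3 was 0.399-fold with IL-25 (0.252 to 0.617) and Cxcl9 0.354-fold (0.145 to 0.784). For Cxcl9, 17 of the 25 TBI+PBS counts lay in 2 monocyte/macrophage-like cells, and microglia-like cells stood at 0.318 and 0.321 CPM.

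In microglia-like cells all 22 measured interferon-stimulated genes were higher with IL-25, with a median of 0.95 (0.85 to 1.02; percentile 100). Ifit2, an interferon-induced RNA-binding protein gene, was 4.36-fold higher (3.70 to 5.16) and Isg15, a ubiquitin-like modifier gene, 2.92-fold (2.68 to 3.19). Ifnb1 went from 1.75 to 41.4 CPM, 23.7-fold (17.5 to 32.8), and the share of cells with its UMI was 0.435% and 6.02%, against 0 of 213 (up to 1.41%, so no background below the TBI+PBS share) and 1 of 631 oligodendrocyte-like cells, whose median depths were 8401 and 3917 UMIs. Proinflammatory genes were higher in 15 of 16 members (0.68, 0.63 to 0.70; percentile 100), with Ccl5 at 3.56-fold (3.23 to 3.92), Tnf at 3.28-fold (3.15 to 3.43) and Il1b at 1.92-fold (1.83 to 2.02). Il12b, a subunit gene of IL-12, was 5.63-fold higher (3.70 to 8.87), whereas Ccl7 was 0.645-fold (0.610 to 0.681). Immediate early genes moved alongside, higher in 13 of 16 (0.63, 0.59 to 0.64; percentile 100), among them Atf3 at 2.34-fold (2.28 to 2.39). Hypoxia and glycolysis genes were higher in 9 of 13 (0.30, 0.24 to 0.37; percentile 99.01), with Vegfa at 3.56-fold (3.13 to 4.06), and their median was reversed within cluster 1 at -0.35. Proliferation genes were higher in 5 of 7 (0.34, 0.18 to 0.72; percentile 97.67), reversed within cluster 1 at -0.25. Within that cluster, which both libraries fill, Cxcl10 was 3.54-fold higher with IL-25 (3.10 to 4.04) and the medians were 1.48 for interferon-stimulated, 0.30 for proinflammatory and 0.35 for immediate early genes. Reactive astrocyte genes were higher in 8 of 10 members in the microglia-like class, 6 of them with intervals above 1 (0.59, 0.29 to 0.80; percentile 99.97), or 0.19 within cluster 1, 0.25 without cluster 22 and 1.0 after subtraction of free RNA.

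Homeostatic genes of the microglia-like class were lower still with IL-25, in 10 of 13 members (-0.57, -0.59 to -0.54; percentile 0.0), with a median of -0.22 within cluster 1. P2ry12 was 0.591-fold (0.582 to 0.601) and Selplg 0.548-fold (0.539 to 0.557), while the fractalkine receptor gene Cx3cr1 was 1.40-fold (1.39 to 1.41). Disease-associated genes were lower in 11 of 18 (-0.41, -0.51 to -0.26; percentile 0.12), but their median was -0.26 with classes from each cell's own marker score, -0.18 among members with at least 200 UMIs and -0.084 within cluster 1. Gpnmb, a lysosomal glycoprotein gene, went from 181 to 5 counts, 0.0248-fold (0.00795 to 0.0589), and the growth factor gene Igf1 was 0.0421-fold (0.0152 to 0.0941). With classes from each cell's own marker score they were 0.398-fold and 0.160-fold, and within cluster 1 Igf1 was 0.210-fold. Spp1 was 0.0915-fold (0.0887 to 0.0944), or 0.147-fold with classes per cell, Lpl 0.364-fold (0.353 to 0.376) and Clec7a, encoding the receptor dectin-1, 2.00-fold (1.80 to 2.23). Mmp12 was 0.109-fold (0.0920 to 0.130), within a matrix list whose median was 0.08 (-0.12 to 0.26; percentile 74.37; 5 of 8 higher). MHC class II genes were lower in 4 of 6 (-0.22, -0.27 to -0.14; percentile 23.76), reversed to 0.15 after subtraction of free RNA and to 0.014 among members with at least 200 UMIs. Complement genes were lower in 5 of 7 (-0.14, -0.14 to -0.13; percentile 24.99). Alternative activation genes were lower in 3 of 4 (-0.16, -0.45 to 0.10; percentile 39.17), with a median of -0.74 without a count minimum, and the mannose receptor gene Mrc1 was 0.102-fold (0.0724 to 0.141). Mid1, a ubiquitin ligase gene, was 11.9-fold higher (10.0 to 14.2), and the potassium channel gene Kcnj12 64.6-fold (11.2 to 2587) from 1 count in TBI+PBS.

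Astrocyte-like cells, with cluster 10 the largest in TBI+PBS and cluster 2 in TBI+IL-25, had 8 of 12 reactive genes higher with IL-25 (0.38, 0.30 to 0.47; percentile 98.64). Cd44, a hyaluronan receptor gene, was 2.25-fold higher (2.18 to 2.33), while Lcn2 was 0.433-fold (0.409 to 0.458) and Gfap 0.833-fold (0.819 to 0.848). Interferon-stimulated genes were higher in 18 of 20 (0.68, 0.63 to 0.83; percentile 100), with Gbp2 at 3.14-fold (2.75 to 3.60). Proinflammatory genes were higher in 9 of 15, 7 of them with intervals above 1 (0.09, 0.02 to 0.44; percentile 94.47), with a median of 0.87 when doublets were kept and 0.70 after subtraction of free RNA. Microglial genes were lower in these astrocyte-like cells, with 11 of 13 homeostatic genes below TBI+PBS (-1.03, -1.16 to -0.85) and medians of -1.78 for MHC class II, -0.76 for complement and -0.13 for disease-associated genes. With doublets kept these turned to 0.053 for homeostatic, 0.71 for MHC class II, 0.48 for complement and 0.14 for disease-associated genes, and after subtraction of free RNA the homeostatic median was 0.35. Hypoxia genes were higher in 10 of 13 (0.40, 0.36 to 0.43; percentile 97.9), with a median of 0.20 when cells weighed equally and 0.59 with median-of-ratios size factors. Adm was 4.53-fold higher (4.22 to 4.87) and Car9, a hypoxia-induced carbonic anhydrase gene, was 20.5-fold higher (11.3 to 41.7). Immediate early genes were again higher, in 14 of 16 (0.59, 0.53 to 0.63; percentile 99.97). Lars2, the mitochondrial leucyl-tRNA synthetase gene, was 11.3-fold higher (10.4 to 12.3) and the small noncoding Y RNA gene Rny1 14.2-fold (9.46 to 22.2), in the library that also held 2.01% ribosomal RNA. Gpx8, encoding a glutathione peroxidase of the endoplasmic reticulum, was 0.104-fold (0.0814 to 0.132). Cnpy1 and Dao, the D-amino acid oxidase gene, were 0.0384-fold (0.0103 to 0.101) and 0.0534-fold (0.0226 to 0.108), and midbrain and hindbrain genes were also lower in these cells, as the closing section weighs.

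In endothelial-like cells (213 against 46), 7 of 10 junction genes were higher with IL-25, 4 of them with intervals above 1 against 3 below, but their median of 0.05 (-0.09 to 0.28; percentile 57.32) had an interval across 0. Cldn5 went from 4796 to 5934 CPM and Cdh5, the VE-cadherin gene, was 1.97-fold higher (1.65 to 2.34). Ocln was 0.395-fold (0.259 to 0.580) and Tjp1 had a ratio of 1.02 (0.792 to 1.30). With classes from each cell's own marker score, Cldn5 was reversed to 0.552-fold, Tjp1 stood at 0.549-fold and Ocln at 0.185-fold, and the junction median was -0.84. Over all cells Cldn5 was 0.248-fold (0.233 to 0.264), beside the 0.164-fold share of endothelial-like cells, Ocln 0.411-fold (0.353 to 0.479) and Tjp1 1.40-fold (1.35 to 1.45). Barrier transport genes were lower in 12 of 12, 9 of them with intervals below 1 (-0.81, -0.96 to -0.65; percentile 0.0). Their median was -1.73 with classes per cell, -1.04 at resolution 0.5 and -0.64 without the cells holding 10 or more microglia marker counts. Slco1a4 was 0.290-fold (0.242 to 0.345), Slc2a1 0.527-fold (0.473 to 0.586) and the monocarboxylate transporter gene Slc16a1 0.576-fold (0.414 to 0.784). Endothelial activation genes were lower in 8 of 8, 3 of them with intervals below 1 (-0.54, -1.06 to -0.29; percentile 5.42), with Icam1 at 0.321-fold (0.0851 to 0.861), but their median was 0.28 when cells weighed equally, -0.19 without the cells rich in microglia markers and -1.40 with classes per cell. Microglial genes were higher in the same comparison, with all 11 measured homeostatic genes above TBI+PBS, only 4 of them with intervals above 1 (0.39, 0.22 to 0.79) and medians of 1.39 for disease-associated and 1.25 for complement genes. Without the cells rich in microglia markers these were 0.18, -0.37 and -0.50, and the homeostatic median was 1.25 with classes per cell, 0.056 with doublets kept and -0.13 at resolution 0.5. Reactive astrocyte genes were lower in 4 of 5 members, with 1 interval below 1 and 1 above (-0.70, -1.05 to -0.20; percentile 1.17).

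Angiogenesis genes of endothelial-like cells were higher in 5 of 8 (0.52, 0.25 to 0.66; percentile 98.53), with the apelin gene Apln at 2.86-fold (1.93 to 4.19) and the VEGF receptor gene Kdr at 1.67-fold (1.35 to 2.04). That median was reversed to -0.11 among members with at least 200 UMIs and to -0.66 with classes from each cell's own marker score. Interferon-stimulated genes were higher in 13 of 14, 8 of them with intervals above 1 and the other member below (0.73, 0.45 to 0.97; percentile 100), with Isg15 at 2.62-fold (1.95 to 3.50). Immediate early genes were higher in 14 of 16, 10 of them with intervals above 1 (0.87, 0.72 to 0.99; percentile 100), with Egr1 at 5.59-fold (4.33 to 7.23), and their median was 1.43 with classes per cell. Hypoxia genes split evenly (-0.06, -0.25 to 0.17; percentile 32.09), with medians of 0.18 without a count minimum and -0.28 without the cells rich in microglia markers. The chemokine genes Ccl3 and Ccl4 were 34.1-fold (22.1 to 54.9) and 13.8-fold higher (11 to 17.4), but 97.6% of their counts lay in 5 cells. With classes per cell they were 7.90-fold and 7.18-fold higher, at resolution 0.5 17.7-fold and 7.07-fold, and with cells weighed equally 10.8-fold and 9.52-fold. Ccl3 was 16.7-fold higher with doublets kept and Ccl4 63.7-fold after subtraction of free RNA. Without the cells holding 10 or more microglia marker counts, their ratios were 1.29 and 0.919, from 57 counts in TBI+PBS and 9 in TBI+IL-25 together, and the immediate early median was 0.10. Igfbp4, an insulin-like growth factor binding protein gene, had 136 counts in TBI+PBS and 1 in TBI+IL-25, a ratio of 0.0402 (0.00101 to 0.228), or 0.236 with cells weighed equally. Isyna1, the inositol-3-phosphate synthase gene, was 0.0953-fold (0.0195 to 0.283), and Adgrl3, an adhesion receptor gene, went from 69 to 0 counts, at least 4.21-fold lower.

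In oligodendrocyte-like cells (213 against 631), the stress gene Gadd45b was 13.1-fold higher (11.4 to 15.0), the immediate early gene Egr3 25.5-fold (8.48 to 126) from 3 counts, and Flnc, encoding filamin C, 11.9-fold (8.43 to 17.2). Their immediate early list was higher in 11 of 16 members (0.80, 0.62 to 0.89; percentile 100), with a median of 1.31 when doublets were kept. Spp1, abundant in the microglia-like cells of TBI+PBS, was 0.0221-fold (0.0100 to 0.0425), or 0.209-fold with doublets kept, 0.0984-fold with classes per cell and 0.0929-fold with cells weighed equally. All 12 measured homeostatic microglia genes were lower in these oligodendrocyte-like cells too, 9 of them with intervals below 1 (-1.10, -1.30 to -0.83), with medians of -0.57 for disease-associated and -1.11 for complement genes. With doublets kept these were 0.30, 0.43 and 0.65, and with classes per cell -0.43, 0.38 and 0.28. After subtraction of free RNA the homeostatic median was -3.71 and the complement median -6.50. The homeobox gene Barx2 went from 60 to 0 counts, at least 25.6-fold lower, and Art3, an ADP-ribosyltransferase gene, was 0.0150-fold (0.00180 to 0.0557).

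**Figure D3:**
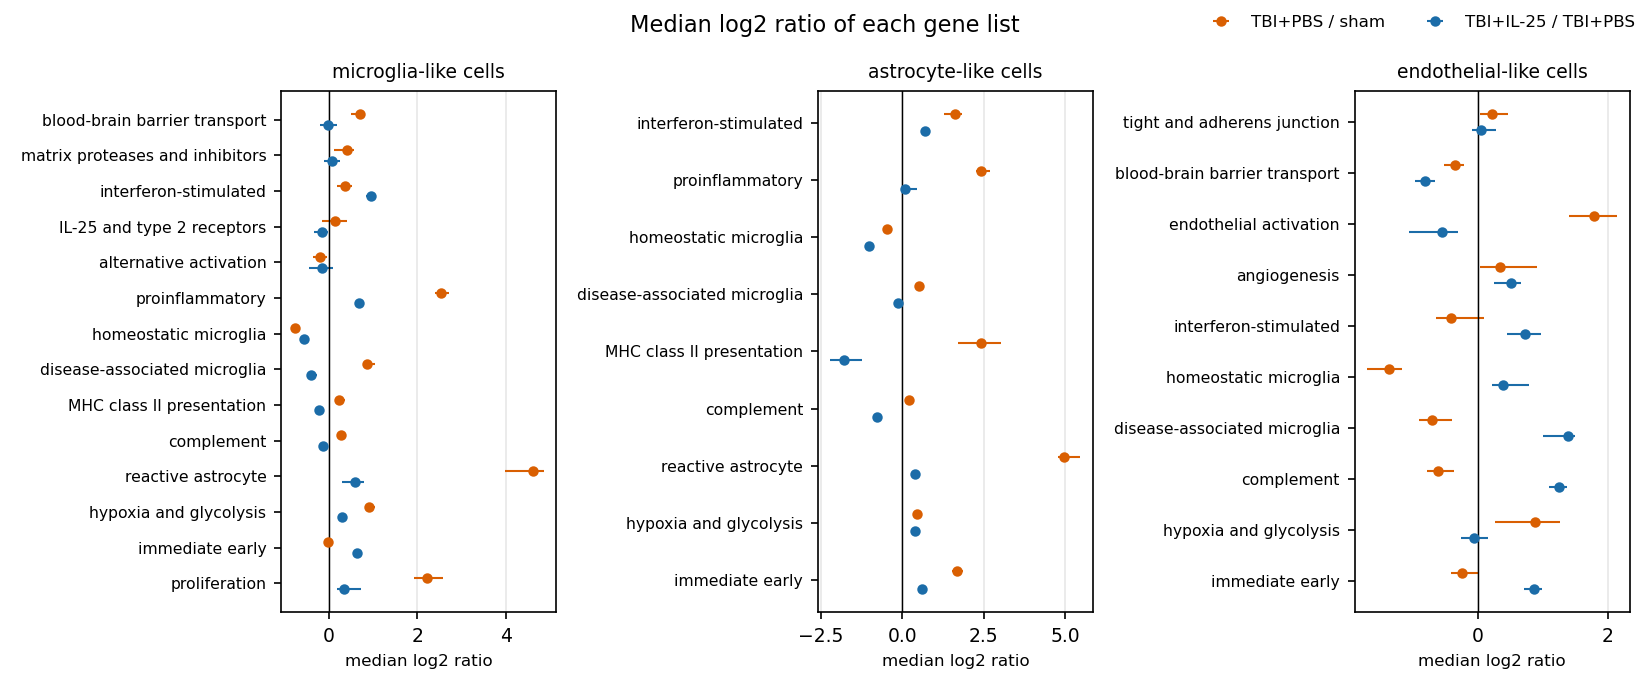
Median log2 CPM ratio of each fixed gene list by class, for TBI+PBS against sham and TBI+IL-25 against TBI+PBS, with intervals for counting error alone. In microglia-like cells, homeostatic microglia genes were below 0 in both comparisons (-0.76 and -0.57). Disease-associated genes of that class stood at 0.86 and then -0.41, or -0.084 within cluster 1.

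The series also concerns ILC2, innate lymphocytes that answer IL-25 with IL-13. No cluster or sub-cluster was named ILC2-like, but a few such cells could not form a cluster, so this sets no bound on their share. Single cells with several ILC2 genes are described in the closing section. The 167 T cell-like cells, clustered again, gave T cell-like groups of 57 (0 sham, 2 TBI+PBS and 55 TBI+IL-25 cells), 40 (6, 23 and 11) and 15 cells (1, 7 and 7), the last led by Il17a and Trdc, and 12 natural killer-like cells (2, 9 and 1). The rest were an unnamed group of 29 led by MHC class II genes (4, 19 and 6) and groups of 8 (1, 2 and 5) and 6 cells (0, 3 and 3) that carried microglia and astrocyte markers. The MHC class II gene Cd74 had 0, 664 and 2 counts in the class. The share and expression ratios of T cell-like cells therefore compare different mixtures. Among type 2 cytokines, Il13 had 0, 0 and 1 counts over all cells and Il5 0, 2 and 2, in the order sham, TBI+PBS and TBI+IL-25. Within T cell-like cells, Il4 had 0, 0 and 3 counts, Il5 0, 0 and 1, Areg 0, 9 and 1, Il10 0, 0 and 1, and Il9 and Il13 none. For Il13, Il5 and Il4 these counts were too few to show a difference. Areg, the amphiregulin gene, had a T cell-like ratio of 0.127 with IL-25 (0.0029 to 0.916), but all 9 TBI+PBS counts lay in 1 cell. Over all cells Areg had 0, 89 and 10 counts, in 0, 19 and 8 cells. These were 0.184% of TBI+PBS and 0.0591% of TBI+IL-25 cells, or 0.0525% and 0.0166% after thinning to 1000 UMIs. The 0 in oligodendrocyte-like cells allows up to 1.41% and 0.475%, too wide to serve as a background.

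Receptors for the axis were measurable. Il17rb, the IL-25 receptor chain, had 18, 28 and 43 counts over all cells, with ratios of 1.06 for TBI+PBS against sham (0.569 to 2.04) and 1.51 for TBI+IL-25 against TBI+PBS (0.917 to 2.52). Cells with an Il17rb UMI were 0.207%, 0.272% and 0.310% of kept cells, and 0.0123%, 0.0420% and 0.0746% after thinning to 1000 UMIs, which left out 558, 772 and 1465 shallower cells. In oligodendrocyte-like cells, with median depths of 10324, 8401 and 3917 UMIs, the shares were 6.82%, 6.10% and 2.22%. After thinning they were 0 of 44 (up to 6.82%), 0.957% and 0.337%, with 2 cells each in TBI+PBS and TBI+IL-25, too few to show a difference. This class therefore gives no background for Il17rb. Il1rl1, the IL-33 receptor gene, had 142, 206 and 209 counts, with ratios of 0.993 (0.798 to 1.24) and 0.998 (0.819 to 1.22). Of these counts, 139, 195 and 195 lay in microglia-like cells and 0, 4 and 6 in T cell-like cells. The ratios therefore describe mainly microglia-like cells and not lymphocytes. Cells with an Il1rl1 UMI were 1.45%, 1.80% and 1.43%, or 0.246%, 0.472% and 0.307% after thinning. The 0 in oligodendrocyte-like cells allows up to 6.82%, 1.41% and 0.475%, which bounds no background for the sham or the thinned shares. Il4ra was 2.46-fold higher in TBI+PBS than in sham (2.32 to 2.61) and 0.794-fold with IL-25 (0.762 to 0.828). Il13ra1, an IL-13 receptor chain gene, had ratios of 0.992 (0.939 to 1.05) and 1.38 (1.32 to 1.44), and Il17ra of 0.962 (0.910 to 1.02) and 0.886 (0.841 to 0.934). In microglia-like cells the receptor list had a median of -0.16 with IL-25 (-0.35 to -0.01; percentile 33.07), with 5 of 7 lower, 3 of them with intervals below 1 against 1 above.

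The TBI+PBS library enters both comparisons, which by chance alone turns their ratios opposite ways. Ratios went opposite ways for 44.4% of 12854 genes in microglia-like cells and 35.5% of 14033 genes in astrocyte-like cells. Simulated unchanged libraries gave 66.0% and 65.0% with counting error, and 66.7% in both classes with a spread between libraries added. The covariance of the log2 ratios was 0.02 and 0.15, against simulated values of -0.01 and -0.01 with counting error and -0.23 and -0.28 with spread. Of the 24 named genes in the 4 classes, 12 stay named for TBI+PBS against sham and 11 for TBI+IL-25 against TBI+PBS when at least 200 UMIs are required.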

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

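The tests on mixed droplets, on free RNA and within cluster 1 were chosen only after the results were seen, whereas the dissociation test and both regional tests were set before their results.

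Ribosomal RNA genes, left out of the gene comparisons, stood apart in the TBI+IL-25 library. Rn18s-rs5 stood at 7893 CPM of the whole library there, against 367 in sham and 450 in TBI+PBS. The mitochondrial ribosomal RNA mt-Rnr1 stood at 4684 CPM, against 250 and 336. Its partner mt-Rnr2 stood at 7498 CPM, against 1137 and 1248.

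Some lists stood out because they went up in 1 class and down in another, each median with its interval clear of 0 and near the end of its matched random lists. The differences of the medians, which were not tested, are given on the log2 scale. In TBI+PBS against sham, homeostatic microglia genes in oligodendrocyte-like cells stood above those in microglia-like, astrocyte-like, endothelial-like and neuroblast-like cells by 1.42, 1.14, 2.01 and 1.34. Disease-associated genes in microglia-like, astrocyte-like and oligodendrocyte-like cells stood above those in endothelial-like cells by 1.56, 1.21 and 1.40. Complement genes in oligodendrocyte-like cells stood above those in endothelial-like cells by 2.45, and barrier transport genes in microglia-like cells by 1.06. In TBI+IL-25 against TBI+PBS, disease-associated genes in endothelial-like cells stood above those in microglia-like and oligodendrocyte-like cells by 1.79 and 1.96, and complement genes above those in astrocyte-like and oligodendrocyte-like cells by 2.01 and 2.36. Most of these pairs involve microglial genes in cells of another class, and many of these medians turned under some of the other settings.

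Cxcl10 in microglia-like cells was 4.11-fold higher in TBI+IL-25 than in TBI+PBS. A response to tissue digestion was tested in the cells whose share of immediate early counts lay below the TBI+PBS median, 2245 in TBI+IL-25 and 2299 in TBI+PBS, and Cxcl10 was still 2.85-fold higher there (2.70 to 3.01). A larger share of cells in the clusters that came mostly from TBI+IL-25 was tested within cluster 1, where the ratio was 3.54 (3.10 to 4.04). The first value argues against digestion as the whole cause, although the smaller ratio leaves room for a part. The second shows a difference inside cluster 1. That cluster held 331 of the 3092 Cxcl10 counts of this class in TBI+PBS, and 698 counts in TBI+IL-25. It therefore cannot tell how much the sizes of the other clusters contributed. An effect of IL-25, a difference between animals and a difference in library quality may each contribute and cannot be separated with 1 library per group, and none of them was tested.

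Ccl3, Ccl4 and Cxcl10 counts in endothelial-like cells were together 18.5-fold higher in TBI+IL-25 than in TBI+PBS (15.3 to 22.4). Without the cells that held 10 or more microglia marker counts, 6 of 46 and 11 of 213, the ratio was 0.905 (0.396 to 1.83). Free RNA spread over all droplets would have placed the counts in many cells, but 97.6% of the Ccl3 and Ccl4 counts in TBI+IL-25 lay in 5 cells. Droplets with microglial RNA beside an endothelial cell are therefore a candidate source of these counts. The 9 counts left in 40 cells are too few to exclude a smaller endothelial difference in either direction.

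Genes of the midbrain and hindbrain were lower in the astrocyte-like cells of TBI+IL-25 than in those of TBI+PBS, with En1 at 0.271, 5.80 and 0.688 CPM in sham, TBI+PBS and TBI+IL-25. Most of the genes that had been looked at were also lower in sham than in TBI+PBS, with 2, 105 and 4 counts of Cnpy1, 4, 72 and 7 of En2 and 29, 151 and 8 of Dao. The held-out genes differed little between sham and TBI+PBS, with Irx1 at 10.9, 12.8 and 4.28 CPM. A regional difference may thus touch TBI+PBS against sham as well, where it was not tested. If the tissue pieces came from different brain regions, telencephalon genes should lie above midbrain and hindbrain genes that had not been looked at. Their medians differed by 1.16 on the log2 scale (0.89 to 1.48), as different regions would predict. However, only 3 of the 10 held-out genes, Irx1, Irx2 and Irx3, had enough counts. Irx5 of the same gene family, at 0.214-fold (0.172 to 0.263), was among the genes already looked at. The held-out genes were therefore not independent of those genes. A general loss of regional genes would lower telencephalon genes too, and their median of -0.42 (-0.53 to -0.30) lay between the bounds set for it, so it cannot be told apart from no such loss. A biological difference between the groups was not tested and stays open.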

How the results depend on the processing

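The settings within 1 cluster, without mixed endothelial-like cells, without shallow clusters, without cluster 22, with cluster 6 as astrocyte and without mitochondrial, ribosomal and Malat1 counts were chosen after seeing the data, the others before. Over 169 results and 21 settings, 1767 of 2088 alternatives kept the value within its counting interval, 286 moved it without turning a called direction and 35 put it on the other side of no change, 2 of them on few counts as given below. For the 26 leading results the value was kept in 214 of 253. Both tallies pool settings that could not move most values with settings that could, so they do not measure robustness. With cluster 6 as astrocyte, which changes only 1 cluster's name, 144 values were kept and 3 moved. With classes from each cell's own marker score, 87 were kept, 54 moved and 5 reversed. Within cluster 4, 3 were kept, 16 moved and 1 reversed. No paired analysis was possible because the groups share only replicate number 1 and no test was made. Endothelial-like values rest on 36 sham and 46 TBI+IL-25 cells, and assigning cells anew moved some of them beyond their counting intervals. Below, the first comparison is TBI+PBS against sham and the second TBI+IL-25 against TBI+PBS. Apart from the count minimum, which leaves fewer members, the cause was not tested.

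With classes from each cell's own marker score, Cldn5 in endothelial-like cells reversed to 0.552-fold in the second comparison, as did the angiogenesis median (-0.66), and the interferon-stimulated median in microglia-like cells reversed to -0.41 in the first. Shares moved to 0.702 and 0.864 for microglia-like cells in the first and second comparison, and in the second to 1.04 for astrocyte-like and 0.314 for endothelial-like cells. Cxcl10 in microglia-like cells moved to 4.36 and 4.38, the homeostatic median to -0.59 and -0.59, the interferon-stimulated median to 1.16 in the second and the junction median to -0.84 in the second.

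Among members with at least 200 UMIs, the angiogenesis median reversed to -0.17 and -0.11 and the MHC class II median to 0.014 in the second, while the interferon-stimulated median of microglia-like cells moved to 0.16 in the first. Of 24 named genes, 12 stayed in the first and 11 in the second. After subtraction of free RNA, the MHC class II median reversed to -0.0665 and 0.15, and the endothelial-like Cxcl10 ratio moved to 189. Without mixed endothelial-like cells, that ratio became 0.0 and that of Ccl4 0.919, but the counts left (7 of Cxcl10 in 202 cells against 0 in 40, and 57 of Ccl3 and Ccl4 against 9) give no direction.

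With the mean over cells, endothelial activation reversed to 0.28 in the second. Cxcl10 in microglia-like cells moved to 3.97 and 4.57, the homeostatic median to -0.63 and -0.68, and the interferon-stimulated median to 1.08 in the second. With median-of-ratios size factors, the immediate early median of microglia-like cells reversed to 0.13 in the first, Cxcl10 moved to 5.74 and 4.33, the homeostatic median to -0.61 and -0.49 and the interferon-stimulated median to 1.02 in the second.

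The astrocyte-like share ratio moved to 1.17 and 1.12 at resolution 0.5 and with cluster 6 as astrocyte, to 1.16 and 1.16 without shallow clusters, and to 1.07 in the second with the stricter cell filter. Without shallow clusters the immediate early median of microglia-like cells reversed to 0.023 in the first. Within cluster 4 (first comparison), the interferon-stimulated median reversed to -0.078, Cxcl10 moved to 1.41 and the homeostatic median to -0.18. Within cluster 1 (second), the hypoxia and proliferation medians reversed to -0.35 and -0.25, Cxcl10 moved to 3.54, the homeostatic median to -0.22 and the interferon-stimulated median to 1.48. The setting with no cell filter kept every value it was run on within its counting interval. It concerns only the 18 sham, 43 TBI+PBS and 55 TBI+IL-25 cells that failed the filter, too few to move most values.

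Microglial lists in other classes turned often. With doublets kept in the second comparison, the medians became 0.053 (homeostatic), 0.14 (disease-associated), 0.71 (MHC class II) and 0.48 (complement) in astrocyte-like cells, and 0.30 (homeostatic), 0.43 (disease-associated) and 0.65 (complement) in oligodendrocyte-like cells. With classes per cell, the latter had 0.38 (disease-associated) and 0.28 (complement). Subtraction of free RNA gave homeostatic medians of 1.23 in astrocyte-like and 2.49 in neuroblast-like cells in the first, and 0.35 (homeostatic) and 0.29 (disease-associated) in astrocyte-like cells in the second, where size factors gave 0.068 (disease-associated). Without mixed endothelial-like cells, complement became 0.28 in the first and -0.50 in the second and disease-associated genes -0.37 in the second. The endothelial-like homeostatic median was -0.13 in the second at resolution 0.5, and the oligodendrocyte-like -0.065 in the first with the mean over cells.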

Other observations

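All of the values below were chosen only after the data were seen, apart from the fixed genes and lists, and no test is attached to them.

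Il33, which encodes an alarmin that acts on ILC2, was most abundant in oligodendrocyte-like cells. It stood at 764 CPM in sham, 921 in TBI+PBS and 3214 in TBI+IL-25, 3.49-fold higher with IL-25 (3.32 to 3.67). Cells with an Il33 UMI made up 70.5%, 65.3% and 91.9% of this class, while 0.681%, 1.30% and 2.85% of microglia-like cells held one, at median depths of 3913, 4746 and 4731 UMIs against 10324, 8401 and 3917 in oligodendrocyte-like cells. Astrocyte-like cells stood at 116, 114 and 145 CPM. Over all cells Il33 was 2.58-fold higher with IL-25 (2.49 to 2.67). Il25 itself had 15, 6 and 23 counts, of which 12, 3 and 9 lay in astrocyte-like and 2, 2 and 14 in choroid plexus-like cells, at 0.814, 0.146 and 0.442 CPM and at 4.32, 3.76 and 12.5 CPM. Microglia-like cells had none, with limits of 0.153, 0.119 and 0.107 CPM.

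Arg1, the arginase-1 gene often used to mark alternative activation, was 0.251-fold over all cells with IL-25 (0.235 to 0.268), beside the smaller share of monocyte/macrophage-like cells. Within that class it stood at 1745 CPM in TBI+PBS and 1773 in TBI+IL-25, a ratio of 1.02 (0.95 to 1.09). The macrophage gene Chil3 had a ratio of 1.08 (0.920 to 1.26), Il1b of 0.907 (0.845 to 0.973), Mrc1 of 0.620 (0.470 to 0.807) and the monocyte chemokine gene Ccl2 of 0.569 (0.518 to 0.624). The alternative activation list of this class had a median log2 ratio of 0.02 (-0.04 to 0.39), at percentile 84.5, with 6 of 11 members higher, or -0.63 with classes from each cell's own marker score.

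Cells with at least 2 of 5 core ILC2 genes (Gata3, Il1rl1, Il17rb, Il13 and Il5) numbered 0 in sham, 2 in TBI+PBS and 4 in TBI+IL-25, of which 0, 0 and 3 had no Cd3 count. A T cell-like cell of TBI+IL-25 with 4555 UMIs held 5 counts of Gata3, 2 of Il1rl1, 1 of Il5 and 7 of Il7r and no Cd3 count. The only Il13 UMI lay in a cell of the monocyte/macrophage-like cluster with 9681 UMIs, 6 counts of the mast cell and basophil gene Cpa3 and 2 of Mcpt8. Cells with a Gata3 UMI made up 0.0690%, 0.204% and 0.118% of kept cells, or 0.0123%, 0.0525% and 0.0414% after thinning to 1000 UMIs. The 0 in oligodendrocyte-like cells allows up to 6.82%, 1.41% and 0.475%, too wide to serve as a background.

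Malat1, a nuclear long noncoding RNA, took 8.02% of UMIs in sham, 6.34% in TBI+PBS and 5.08% in TBI+IL-25. The cluster led by interferon genes (cluster 18) held 79, 46 and 242 microglia-like cells, and the cycling cluster (cluster 19) 17, 109 and 241.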
